A study of Caenorhabditis elegans with 12 samples.

How the data were processed

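RNA was taken from whole C. elegans described as young adults that were not yet fertile, grown at 20 °C on agar plates with OP50 bacteria. The 12 libraries were made with a stranded mRNA kit for the Illumina platform and fall, by the genotype label of each sample, into 4 groups of 3: wild type, the isp-1 mutant, and the double mutants isp-1;sod-3 and isp-1;sod-5. The double mutants are also called the sod-3 double mutant and the sod-5 double mutant. According to the design text, RNA was isolated from 9 biological replicates per genotype and 3 isolates were combined into each library, while the pooling label of each sample says none. Replicate numbers come from the sample titles. They name libraries and were not used to pair them.

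The deposited matrix holds counts per 1000000 reads in genes (CPM) for 14326 genes in the 12 libraries, and the authors' processing notes name bcl2fastq 2.17.1.14, FastQC 0.11.3, Subread 1.5.0, featureCounts 1.4.6, edgeR 3.14.0 and R 3.3.0 with the genome build WBcel235, without saying which tool did what. The counting strand is not given in the sources used here. Each column of the matrix summed to 1000000, so the values carry no further normalization factor. Every value was a whole multiple of the value of 1 read in its library within a tolerance of 0.001 reads (100.0% of values), which gave back the read counts and a total per library. Every gene in the matrix exceeded 1 CPM in at least 2 libraries, a filter of the authors. Gene names, coordinates, gene types and exon lengths came from the Ensembl annotation of WBcel235. It held 14250 of the 14326 identifiers and named 13808 of them, 13695 genes being protein coding. A genome sequence was not used here, so GC content was not examined.

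The total of reads in genes ran from 5438798 to 155071752 per library, a ratio of 28.5, so 1 read was worth 0.184 CPM in the shallowest library and 0.00645 CPM in the deepest. A chi-square comparison of read counts between libraries of the same group found no pair that agreed within sampling noise, and no library was dropped or merged.

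Differential expression was tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with trend and robust options) on log2(CPM + 0.5). Genes above 1 CPM in at least 3 of the 12 libraries were tested, which left 14013. All 12 libraries entered one fit with genotype as the factor, p-values were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Errors of log2 fold changes are limma standard errors (SE), and levels are given as mean ± SD over 3 libraries. The fold printed for a gene comes from the same fit on log2(CPM + 0.5). Where a level is low, the added 0.5 makes the fold smaller than the ratio of the printed mean CPM. Rankings by fold change carry the same limit. Limma was tested on simulated data made from these libraries, in the comparison of isp-1 with wild type. It recovered 44.8% of 67 genes changed 1.5-fold, 85.1% of 67 genes changed 2-fold and 100% of 66 genes changed 4-fold, with 4 unchanged genes called. With edgeR the shares were 40.3%, 85.1% and 100%, with 6 unchanged genes called. The changed genes were drawn from those with a mean of at least 5 CPM, and each gene had the same spread in all groups. These shares thus do not cover lower genes or comparisons with the more variable double mutants. Where a gene lay below the expression filter, an exact two-sided permutation test was run on CPM, whose smallest possible p at 3 against 3 is 0.1.

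The 45 gene lists (stress responses, metabolism, protein families, tissues and cell types), the comparisons, the tests and the rule for naming genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists. In the same simulated data camera called a planted list of 30 genes and did not call a list with no change. Genes were drawn independently there, so this does not test the preset correlation. Counts of list members past the threshold are given over all tested genes and adjusted over the list alone. Named genes are isp-1 and the 5 sod genes, the 8 largest rises and 8 largest falls with adjusted p below 0.05, a mean of at least 5 CPM, no overlap of libraries and a locus name, and up to 4 members of each described list with the smallest adjusted p. For the double mutants against wild type this covers only isp-1, the sod genes and counts. Any other gene is said to be chosen after its values were seen.

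The overlap of comparisons that share libraries was set against 100 simulated data sets in which the residuals of the 12 libraries were regrouped with no effect, and against the product expected from independent lists. Alternatives covered the filter, the pseudocount, the scaling (median centring, quantile normalization, TMM factors), edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a replicate block, stricter thresholds, fits with the compared groups alone, and leaving out each of the 12 libraries. Lists were also tested with camera at an estimated correlation and with fry (limma with statmod 1.5.0). Weights per library, removal of a trend with exon length in each library by a lowess curve of span 0.3, and leaving the ribosomal RNA gene rrn-3.1 out of the totals were added after the data had been seen.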

Results

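Messenger RNA was sequenced from whole young adult worms of 4 genotypes with 3 libraries each. The isp-1 gene encodes the Rieske iron-sulphur protein of respiratory complex III, and sod-3 and sod-5 encode a mitochondrial and a cytosolic superoxide dismutase. The series compares isp-1 with wild type and asks what the loss of either dismutase changes in the isp-1 background. Totals of reads in genes, in units of 1000000 reads, were 32.21, 18.72 and 41.91 in wild type replicates 1 to 3 and 16.23, 11.48 and 8.71 in isp-1. They were 155.07, 14.93 and 15.49 in isp-1;sod-3 and 10.63, 5.44 and 20.01 in isp-1;sod-5. The median within-group SD of log2 values was 0.12 in wild type, 0.13 in isp-1, 0.22 in isp-1;sod-3 and 0.27 in isp-1;sod-5. With all 12 libraries in one fit, p-values rest on the spread between libraries within groups, pooled over all 4 genotypes. The wider spread of the double mutants thus also enters the comparison of isp-1 with wild type. In turn the narrower spread of wild type and isp-1 enters the comparison of the double mutants with each other, where p-values may be too small. The design text describes pooled isolates and the sample labels describe none, so this spread may be partly technical.

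The level of sod-3 (WBGene00004932, chromosome X, 17092753 to 17094306) rose in isp-1 and fell when the gene was mutated. It was 2.08 ± 0.472 CPM in wild type, 19.8 ± 1.03 CPM in isp-1, 1.12 ± 0.853 CPM in isp-1;sod-3 and 19.4 ± 5.87 CPM in isp-1;sod-5 (SD, n = 3 each). The rise in isp-1 was 7.92-fold (log2 2.99, SE 0.38, adjusted p = 0.000247). In the sod-3 double mutant the gene fell by 3.83 on the log2 scale against isp-1 (SE 0.38, adjusted p = 0.000123), a 14.2-fold lower level. Its 3 libraries there held 23, 22 and 27 reads of the gene, or 0.148, 1.47 and 1.74 CPM. The sod-5 gene (WBGene00007036, chromosome II, 4417633 to 4419130) was close to the limit of these libraries, at 0.172 ± 0.0853 CPM in wild type, 0.418 ± 0.267 CPM in isp-1, 1.15 ± 0.411 CPM in isp-1;sod-3 and 0.179 ± 0.175 CPM in isp-1;sod-5. Its mean was lower in the sod-5 double mutant than in isp-1 with an exact two-sided permutation p = 0.3, and higher in the sod-3 double mutant than in isp-1 with an exact p = 0.1, the smallest p that 3 against 3 allows. A test whose smallest p is 0.1 cannot pass 0.05, so it does not decide whether the sod-5 transcript was lost.

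The isp-1 gene itself (WBGene00002162, chromosome IV, 8134016 to 8136055) was at 295 ± 18.5 CPM in wild type and 339 ± 8.3 CPM in isp-1 (log2 0.20, adjusted p = 0.221). The other dismutase genes did not pass the test in isp-1 or between isp-1 and either double mutant. Mitochondrial sod-2 (WBGene00004931) was at 81 ± 6.46 CPM in wild type and 96.7 ± 2.13 CPM in isp-1 (adjusted p = 0.0551). Cytosolic sod-1 (WBGene00004930) was at 131 and 139 CPM (adjusted p = 0.559), and extracellular sod-4 (WBGene00004933) was at 7.41 ± 0.51 and 9.01 ± 1.05 CPM (adjusted p = 0.313). As a list, the 4 measured dismutase genes had 1 member up and 0 down, and 2 up adjusted over the list alone. Their camera adjusted p = 0.0418 became adjusted p = 0.456 with an estimated correlation, and adjusted p = 0.07 without isp-1 replicate 2, with the call also lost without wild type replicate 1, isp-1;sod-3 replicate 2 or isp-1;sod-3 replicate 3.

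**Figure D1:**
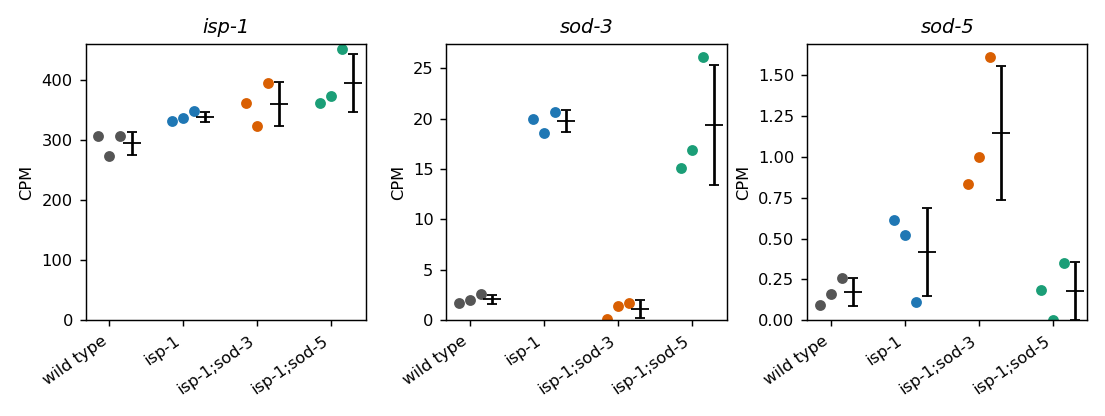
Level in CPM of isp-1, sod-3 and sod-5 in the 12 libraries (points) with the mean and SD of the 3 libraries of each genotype (dash and bar). The mean of sod-3 is 19.8 CPM in isp-1 and 1.12 CPM in isp-1;sod-3, while sod-5 has group means between 0.172 and 1.15 CPM.

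The isp-1 mutant differed from wild type in 2798 genes, with 1345 higher and 1453 lower, of which 430 and 1050 changed at least 2-fold. The share of called genes that rose was 48.1%, against 39.9% with median centring, 50.2% with quantile normalization, 45.6% with TMM factors, 45.2% with the length trend removed and 55.2% with rrn-3.1 left out, so the direction of the majority depends on the scaling. The largest changes named here and below are those among genes with a locus name, a mean of at least 5 CPM over the 12 libraries and no overlap of libraries, and some genes outside these limits changed more. The largest such rise was that of the cytochrome P450 gene cyp-13B1 (22.3 ± 7 CPM against 0.394 ± 0.127 CPM, SD, n = 3 each, 24.8-fold, log2 4.63, SE 0.26, adjusted p = 1.66e-07). Next were dpy-14, which encodes a cuticle collagen (21.1-fold, SE 0.51 on the log2 scale, adjusted p = 0.000245), and hch-1, an astacin protease (log2 4.03, adjusted p = 6.06e-05). They were followed by sysm-1 (log2 3.56, adjusted p = 1.43e-05), the collagen gene dpy-17 (log2 3.48, adjusted p = 4.84e-05), bath-13 (log2 3.35, adjusted p = 4.81e-08) and the C-type lectin gene clec-17 (log2 3.19, adjusted p = 6.75e-06). The cytochrome P450 gene cyp-14A4 was also at log2 3.35 (adjusted p = 0.0137), with an adjusted p of 0.0509 without wild type replicate 1. The largest such fall was that of fat-7, a stearoyl-CoA desaturase gene, from 38.1 to 2.32 CPM (13.6-fold lower, log2 −3.76, SE 0.35, adjusted p = 1.95e-05). The aspartyl protease genes asp-17 and asp-12 were 7.98-fold and 7.93-fold lower (both SE 0.26, adjusted p = 1.09e-05), and the transporter gene pgp-6 fell by 2.87 on the log2 scale (SE 0.19, adjusted p = 9.51e-07). The hedgehog-like gene wrt-4 was at log2 −3.21 (adjusted p = 0.00281), the cuticlin gene cut-2 at log2 −2.61 (adjusted p = 0.00688), idpc-6 at log2 −2.28 (adjusted p = 0.0109) and clec-47 at log2 −2.27 (adjusted p = 0.00044). Of all tested genes, 51.7% had no overlap between the 3 libraries of each genotype, against 10% by chance. The count was 1225, 1177 and 1463 without wild type replicate 1, 2 or 3, and 1111 and 1088 without isp-1 replicate 1 or 3.

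**Figure D2:**
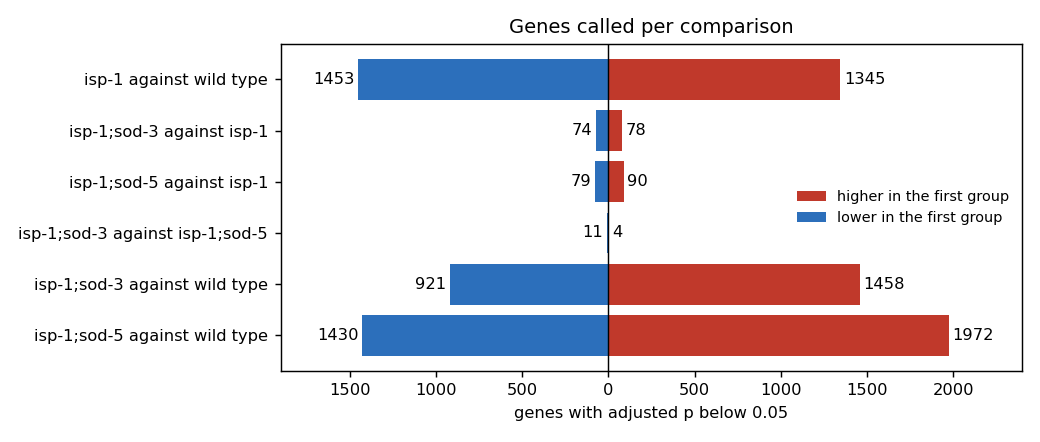
Number of genes called higher (red) or lower (blue) in the first named genotype at an adjusted p below 0.05, for the 6 comparisons. The comparison of isp-1 with wild type has 1345 higher and 1453 lower genes, and the comparison of both double mutants with each other 4 and 11.

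Detoxification genes rose as groups in isp-1. Of 26 measured targets of the oxidative stress regulator SKN-1, 14 rose, 0 fell and 12 did not pass, with the same 14 adjusted over the list alone (median log2 0.76, camera adjusted p = 2.9e-08, and adjusted p = 0.0707 with an estimated correlation). Among them the dehydrogenase gene dhs-8 rose 6.06-fold (adjusted p = 2.9e-06) and the glutathione S-transferase gene gst-4 rose 4.61-fold, from 15.4 ± 1.28 to 73 ± 8.56 CPM (log2 2.21, SE 0.20, adjusted p = 1.43e-05). Of 36 glutathione S-transferase genes 13 rose and 0 fell, or 14 adjusted over the list alone (median 0.53, camera adjusted p = 1.02e-06, and adjusted p = 0.347 with an estimated correlation). These included gst-14 (9.39-fold) and gst-13 (2.75-fold). Of 57 cytochrome P450 genes 21 rose and 3 fell, or 24 and 4 adjusted over the list alone (median 0.53, camera adjusted p = 6.26e-05, and adjusted p = 0.347 with an estimated correlation), with cyp-33C8 up 4.80-fold and cyp-14A1 up 5.31-fold. Of 57 UDP-glucuronosyltransferase genes, which conjugate small molecules, 15 rose and 6 fell, or 19 and 7 adjusted over the list alone (median 0.39, camera adjusted p = 0.00673, and adjusted p = 0.749 with an estimated correlation). Among them ugt-61 rose 3.57-fold and ugt-21 rose 2.62-fold. Of 27 peroxide and thiol antioxidant genes 6 rose and 1 fell, the same adjusted over the list alone (median 0.20, camera adjusted p = 0.0105, and adjusted p = 0.453 with an estimated correlation), with the mitochondrial thioredoxin reductase gene trxr-2 up 2.18-fold (adjusted p = 0.000109).

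Genes of the mitochondrial unfolded protein response also rose. Of 19 measured, 10 rose, 0 fell and 9 did not pass, or 13 and 0 adjusted over the list alone (median log2 0.34, camera adjusted p = 0.00033, and adjusted p = 0.0707 with an estimated correlation). The mitochondrial chaperone gene hsp-6 went from 747 ± 38.6 to 1150 ± 11.6 CPM (1.54-fold, log2 0.62, SE 0.09, adjusted p = 0.000504), the co-chaperone gene dnj-10 rose 1.52-fold and the mitochondrial protease gene ymel-1 rose 1.46-fold. Of 28 genes activated by the insulin-pathway factor DAF-16, 15 rose and 4 fell, or 17 and 4 adjusted over the list alone (median 0.68, camera adjusted p = 3.66e-06, and adjusted p = 0.337 with an estimated correlation). Among them were pck-1, a gluconeogenesis enzyme (3.16-fold, SE 0.10 on the log2 scale, adjusted p = 2.5e-07), the ferritin gene ftn-1 (4.74-fold) and the transhydrogenase gene nnt-1 (3.05-fold). The 17 genes that DAF-16 represses had 5 up and 2 down, or 7 and 2 adjusted over the list alone, and were not called as a list. Of 21 genes of the HIF-1 hypoxia response 10 rose and 1 fell, or 11 and 1 adjusted over the list alone (median 0.53, camera adjusted p = 0.000149, and adjusted p = 0.357 with an estimated correlation). The flavin monooxygenase gene fmo-2 rose 14.4-fold (adjusted p = 7.63e-08), the sulphide oxidation gene sqrd-1 3.05-fold and nhr-57 2.55-fold. Of 19 iron and metal handling genes 5 rose and 0 fell, or 6 and 0 adjusted over the list alone (median 0.51, camera adjusted p = 0.000333, and adjusted p = 0.347 with an estimated correlation). The rises included the metallothionein gene mtl-1 (5.29-fold, adjusted p = 0.00215) and the heme transporter gene hrg-1 (2.12-fold, adjusted p = 0.00258).

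Energy metabolism was covered by several lists. Of 24 glycolysis and gluconeogenesis genes 12 rose and 3 fell, the same adjusted over the list alone (median log2 0.27, camera adjusted p = 0.00033, and adjusted p = 0.337 with an estimated correlation). Besides pck-1, the aldolase gene aldo-1 rose 2.12-fold (adjusted p = 0.000181) and the lactate dehydrogenase gene ldh-1 rose 1.74-fold (adjusted p = 5.09e-05). Of 42 nuclear genes of respiratory complexes II to V 5 rose and 0 fell, or 4 and 0 adjusted over the list alone (median 0.14, camera adjusted p = 0.0128, and adjusted p = 0.808 with an estimated correlation). For 36 nuclear complex I genes the counts were also 5 and 0, or 4 and 0 adjusted over the list alone (median 0.16, camera adjusted p = 0.0164, adjusted p = 0.808 with an estimated correlation, and 0.0942 without wild type replicate 1). Of 27 genes of the tricarboxylic acid and glyoxylate cycles 4 rose and 0 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0194, adjusted p = 0.722 with an estimated correlation, and 0.0565 without wild type replicate 2). The glyoxylate cycle gene icl-1 was at log2 0.91 (adjusted p = 0.00196). Of 48 fatty acid oxidation and lipolysis genes 14 rose and 5 fell, or 14 and 6 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0901), while its member acs-2, an acyl-CoA synthetase gene, rose 6.58-fold (adjusted p = 0.000207). Of 29 fatty acid synthesis and desaturation genes 2 rose and 7 fell, or 2 and 8 adjusted over the list alone (median −0.09, mean −0.41), with fat-7 as above, fat-5 at log2 −1.67 and dgat-2 at log2 −1.13. That list's camera adjusted p = 0.0418 became adjusted p = 0.489 with an estimated correlation and 0.0718 without isp-1 replicate 1, and was also lost without wild type replicate 1, isp-1;sod-3 replicate 2 or isp-1;sod-3 replicate 3.

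Lists of cytosolic ribosomal proteins, the endoplasmic reticulum unfolded protein response, the proteasome and histones were lower in isp-1. Of 81 cytosolic ribosomal protein genes 0 rose and 45 fell, or 62 adjusted over the list alone (median log2 −0.42, camera adjusted p = 1.53e-15, and adjusted p = 0.466 with an estimated correlation). The examples rpl-2 (log2 −0.67, SE 0.12, adjusted p = 0.00325), rps-6 (log2 −0.55, adjusted p = 0.007) and rps-2 (log2 −0.55, adjusted p = 0.00899) were between 1.46-fold and 1.59-fold lower. The 69 mitochondrial ribosomal protein genes had 1 up and 2 down, 0 of them adjusted over the list alone, and were not called (camera adjusted p = 0.176). Of 21 genes of the endoplasmic reticulum unfolded protein response 0 rose and 9 fell, or 11 adjusted over the list alone (median −0.32, camera adjusted p = 0.000929, and adjusted p = 0.347 with an estimated correlation). They included the protein disulphide isomerase genes pdi-6 (log2 −0.74, adjusted p = 0.000486) and pdi-2 (log2 −0.76, adjusted p = 0.00494). Of 33 proteasome genes 0 rose and 3 fell, with 0 adjusted over the list alone (median −0.19, camera adjusted p = 0.000234, and adjusted p = 0.507 with an estimated correlation). Of 19 histone genes 1 rose and 8 fell, or 1 and 11 adjusted over the list alone (median −0.55, camera adjusted p = 0.000208, and adjusted p = 0.347 with an estimated correlation). The core histone genes his-60 and his-40 were 2.35-fold and 2.46-fold lower, and his-24, a linker histone gene, rose 2.52-fold.

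Sperm genes were lower in isp-1, while lists of oocyte and mitotic germline genes were not called. Of 33 major sperm protein genes, which build the sperm cytoskeleton, 0 rose and 24 fell, or 28 adjusted over the list alone (median log2 −1.19, camera adjusted p = 2.79e-10, and adjusted p = 0.466 with an estimated correlation). Among them msp-32 was at log2 −1.72 (adjusted p = 0.00588) and msp-56 was at log2 −1.71 (adjusted p = 0.00819). Of 40 other sperm genes 0 rose and 19 fell, or 31 adjusted over the list alone (median −1.06, camera adjusted p = 1.08e-10, and adjusted p = 0.453 with an estimated correlation). The phosphatase gene gsp-4 and the fertility gene spe-49 were both at log2 −1.54 (adjusted p = 0.00682 and 0.00711). The 36 oocyte and eggshell genes had 2 up and 0 down, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.544). The 49 germline mitosis and meiosis genes had 1 up and 2 down, or 0 and 1 adjusted over the list alone (camera adjusted p = 0.447). The 14 early zygotic embryo genes had 1 up and 0 down, the same adjusted over the list alone. Their camera adjusted p = 0.0418 became adjusted p = 0.456 with an estimated correlation and 0.0671 without isp-1 replicate 1, and was also lost without wild type replicate 3 and with the length trend removed. Collagen genes moved with the sperm genes between libraries of the same genotype, with a within-group correlation of 0.98 between the mean levels of the collagens and of the 40 sperm genes. The mean collagen level, as a log2 deviation from the 12-library mean, was 0.26, 0.22 and 0.27 in wild type, −0.37, 0.04 and −0.49 in isp-1, 0.09, −0.67 and 0.81 in isp-1;sod-3, and −0.53, 0.16 and 0.20 in isp-1;sod-5. Of 150 collagen genes 21 rose and 26 fell in isp-1, or 21 and 42 adjusted over the list alone (median −0.68, camera adjusted p = 0.00496, and adjusted p = 0.851 with an estimated correlation), with col-143 and col-101 both at log2 1.07. The 41 molting genes had 1 up and 5 down, or 1 and 2 adjusted over the list alone (median −0.40, camera adjusted p = 0.00673, and adjusted p = 0.789 with an estimated correlation). The 34 body wall and pharyngeal muscle genes had 0 up and 2 down, with 0 adjusted over the list alone (median −0.27, camera adjusted p = 0.00665, and adjusted p = 0.749 with an estimated correlation).

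**Figure D3:**
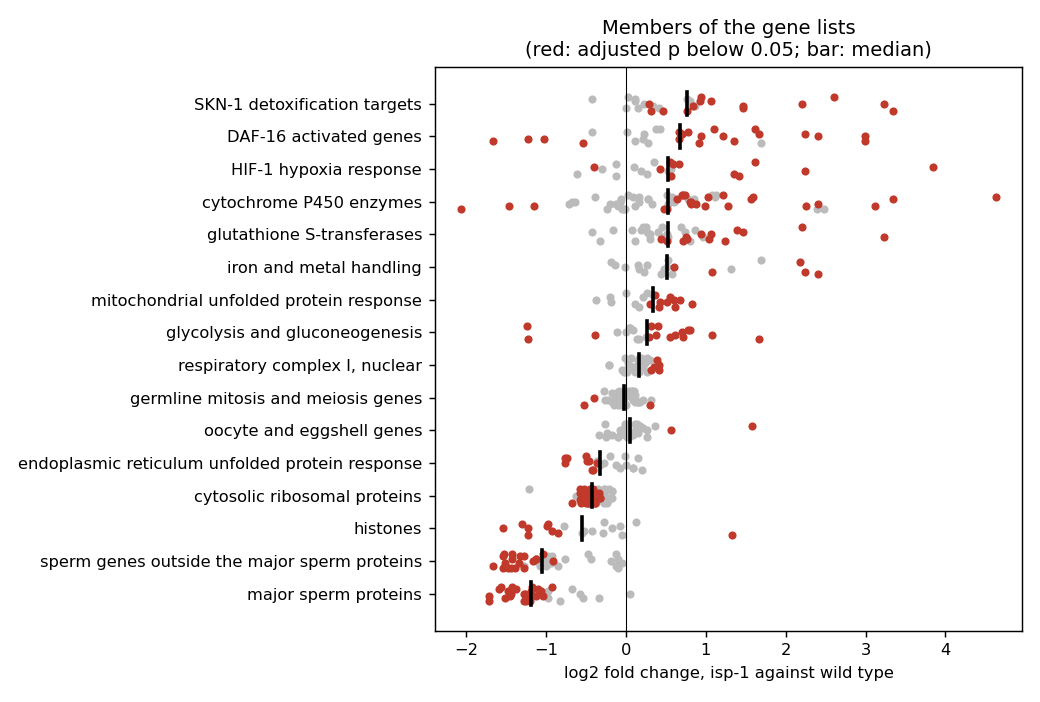
Log2 fold change of isp-1 against wild type for each measured member of 16 gene lists (points, red where the adjusted p is below 0.05), with the median of each list as a black bar. The median is 0.76 for the SKN-1 targets, −0.42 for the cytosolic ribosomal proteins and −1.19 for the major sperm proteins.

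Immune genes changed in both directions in isp-1, and the list of yolk proteins was not called. The lysozyme gene lys-4 fell by 1.56 on the log2 scale (adjusted p = 7.57e-05) and ilys-5 by 1.09 (adjusted p = 0.00056), while the list of 10 lysozymes had 1 member up and 4 down, the same adjusted over the list alone. Its camera adjusted p = 0.0437 became adjusted p = 0.453 with an estimated correlation. It was lost with median centring, with the length trend removed, and without wild type replicate 3, isp-1 replicate 3, any one isp-1;sod-3 library or isp-1;sod-5 replicate 1 or 2, at an adjusted p of 0.07 without wild type replicate 3 and 0.0913 with the length trend removed. Of 25 genes on the list named for the immune kinase PMK-1, 10 rose and 2 fell, or 10 and 3 adjusted over the list alone. Among its members F55G11.8 was at log2 1.64 and irg-1 at log2 −2.1 (adjusted p = 0.000221). Whether each member, irg-1 included, depends on PMK-1 was not tested, so the list is no measure of PMK-1 activity. The camera adjusted p = 0.0448 of this list became adjusted p = 0.646 with an estimated correlation and was lost without wild type replicate 2 or 3, isp-1 replicate 1 or 2, or isp-1;sod-3 replicate 3, up to 0.122 without isp-1 replicate 2, and with rrn-3.1 left out (0.0595). The 93 C-type lectin genes had 17 up and 17 down, or 18 and 18 adjusted over the list alone, and were not called (camera adjusted p = 0.688). The vitellogenin genes, which encode yolk proteins, had 0 up and 2 down of 6, the same adjusted over the list alone (camera adjusted p = 0.324), with vit-3 at log2 −1.46 (adjusted p = 0.00016). The 21 cytosolic heat shock genes had 2 up and 2 down, or 2 and 4 adjusted over the list alone, a median of −0.05, a mean of 0.08 and the camera direction down (adjusted p = 0.619). The 12 mitochondrially encoded genes had 3 up and 0 down, the same adjusted over the list alone (camera adjusted p = 0.176). Lists of intestine, neuronal, neuropeptide, epidermis, gonad sheath and autophagy genes were not called, nor were those of apoptosis genes, epidermal antimicrobial peptides and reported regulators of isp-1 longevity.

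The isp-1;sod-3 double mutant differed from isp-1 in 152 genes, with 78 higher and 74 lower, of which 45 and 51 changed at least 2-fold. The share that rose was 51.3%, against 46.1% with median centring, 44.4% with quantile normalization, 49.7% with TMM factors, 49.6% with the length trend removed and 50.8% with rrn-3.1 left out. Within the same limits, the largest rises were those of the F-box gene fbxa-24 (6.12-fold, log2 2.61, SE 0.37, adjusted p = 0.00217) and the C-type lectin genes clec-43 (4.70-fold, SE 0.20 on the log2 scale, adjusted p = 6.44e-05) and clec-72 (3.53-fold, adjusted p = 0.00154). Next came xdh-1, a xanthine dehydrogenase gene (2.69-fold, adjusted p = 0.000171). The dehydrogenase gene dhs-25 rose 2.32-fold (adjusted p = 6.44e-05), and the heme-responsive gene hrg-2 rose 2.64-fold (adjusted p = 0.0077, and 0.0513 without isp-1 replicate 3). A further C-type lectin gene, clec-17, rose 2.29-fold with an adjusted p of 0.0481 that reached 0.233 when a library was left out. It was above the threshold without any one wild type or isp-1 library, isp-1;sod-3 replicates 2 or 3, or isp-1;sod-5 replicate 2. It was also above with a pseudocount of 0.1 CPM, with CPM above 5, with a replicate block, with only the 2 groups fitted and with eBayes without its trend and robust options. Beside sod-3 itself, the largest falls within these limits were those of dod-24, a gene downstream of DAF-16 (log2 −2.91, SE 0.27, 7.52-fold lower, adjusted p = 6.58e-05), cyp-35C1 (log2 −1.95) and cyp-13B1 (log2 −1.84). The yolk protein gene vit-3 fell from 1010 ± 141 to 292 ± 35 CPM (log2 −1.79, SE 0.18, adjusted p = 0.000112). The protease gene asp-14 was at log2 −1.77 (adjusted p = 0.00281) and the lysozyme gene ilys-5 at log2 −1.71 (adjusted p = 6.44e-05). The gene sysm-1, at log2 −1.68 (adjusted p = 0.0178), lost its call without any one isp-1 library (up to 0.104) and with only the 2 groups fitted. The stress sensor gene ire-1 fell from 152 to 59.6 CPM (log2 −1.34, SE 0.11, adjusted p = 5.09e-05). Of all tested genes 15.6% had no overlap of libraries, against 10% by chance. The count of 152 was 98 without isp-1 replicate 2 and 89 without isp-1 replicate 3.

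Several lists of yolk, immune and detoxification genes were called lower in isp-1;sod-3 than in isp-1, while the epidermal antimicrobial peptides, also immune genes, were called higher. The mean levels of the UDP-glucuronosyltransferases, SKN-1 targets and cytochrome P450 genes overlapped between the libraries of both groups. Of 6 vitellogenins 0 rose and 4 fell, the same adjusted over the list alone (median log2 −0.97, camera adjusted p = 5.31e-09, and adjusted p = 0.437 with an estimated correlation), with vit-4 going from 1630 ± 209 to 567 ± 42.2 CPM. The list weights its 6 genes alike. Their summed share of reads overlapped between the groups, at 4.494, 5.989 and 3.969% in isp-1;sod-3 and 6.915, 5.358 and 6.158% in isp-1. Of 10 lysozymes 0 rose and 2 fell, or 3 adjusted over the list alone (median −0.39, camera adjusted p = 0.000114, and adjusted p = 0.437 with an estimated correlation), with lys-4 at log2 −1.26. Of 17 genes repressed by DAF-16 0 rose and 3 fell, or 5 adjusted over the list alone (median −0.08, camera adjusted p = 0.00095, and adjusted p = 0.437 with an estimated correlation). Of 25 PMK-1 genes 0 rose and 4 fell, or 6 adjusted over the list alone (median −0.08, camera adjusted p = 0.000154, and adjusted p = 0.437 with an estimated correlation). The endoplasmic reticulum unfolded protein response had 0 up and 1 down of 21, or 6 down adjusted over the list alone (median −0.08, camera adjusted p = 0.000114, and adjusted p = 0.437 with an estimated correlation). The 57 UDP-glucuronosyltransferases had 0 up and 3 down, or 2 and 5 adjusted over the list alone (median −0.17, camera adjusted p = 0.000137, and adjusted p = 0.814 with an estimated correlation), with ugt-34 at log2 −1.73. Of 26 SKN-1 targets 0 rose and 2 fell, or 3 adjusted over the list alone, with dhs-8 at log2 −1.46 (adjusted p = 0.00136). That list's camera adjusted p = 0.00891 became adjusted p = 0.437 with an estimated correlation, and 0.124 without isp-1;sod-3 replicate 3. The 57 cytochrome P450 genes had 1 up and 5 down, or 1 and 9 adjusted over the list alone, with a positive median of 0.05 and mean of 0.03 while the camera direction was down (adjusted p = 0.0335, and adjusted p = 0.814 with an estimated correlation). That call was lost with median centring, with the length trend removed and without isp-1 replicate 1, isp-1;sod-3 replicate 1 or isp-1;sod-3 replicate 3, the last at an adjusted p of 0.46. The 36 glutathione S-transferases had 0 up and 1 down, the same adjusted over the list alone, and were not called (camera adjusted p = 0.172). Of 12 epidermal antimicrobial peptides 2 rose and 0 fell, or 4 and 1 adjusted over the list alone (median 0.60, camera adjusted p = 0.0223, and adjusted p = 0.814 with an estimated correlation). That call was lost without isp-1;sod-3 replicate 3 (median 0.34, adjusted p = 0.124) and with the length trend removed (adjusted p = 0.0917). The mitochondrial unfolded protein response list had 0 members changed, 1 up adjusted over the list alone (camera adjusted p = 0.0673), and hsp-6 was at log2 0.29 (adjusted p = 0.204).

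Some lists in this comparison moved without called members, or with the library of highest collagen level. Where 0 members of a list were called here, 0 were called adjusted over the list alone too. Of 81 cytosolic ribosomal protein genes 0 were called and the median was 0.14 (camera adjusted p = 0.00011, adjusted p = 0.837 with an estimated correlation), against 0.07 and 0.0791 without isp-1;sod-3 replicate 3. Of 150 collagens 0 rose and 3 fell, the same adjusted over the list alone, among them col-101 (log2 −1.04) and col-135 (log2 −1.17), yet the list median was 0.49 and the camera direction up (adjusted p = 0.0406, and adjusted p = 0.859 with an estimated correlation). Without isp-1;sod-3 replicate 3 that median was 0.02 and the adjusted p 0.0593. The call was lost too without wild type replicate 1 or 3, isp-1 replicate 1 or 3, isp-1;sod-5 replicate 3, and with a replicate block. The major sperm protein list had 0 called genes and a median of 0.30 (camera adjusted p = 0.00487, and adjusted p = 0.837 with an estimated correlation), which was −0.05 (adjusted p = 0.506) without that library. The 94 neuropeptide genes had 0 called and a median of 0.24 (camera adjusted p = 0.000114, adjusted p = 0.837 with an estimated correlation), or 0.19 and 0.00392 without it. The 12 mitochondrially encoded genes had 0 called and a median of −0.87 (camera adjusted p = 0.000175, adjusted p = 0.575 with an estimated correlation). In all, 22 of 45 lists were called, and 11 without isp-1;sod-3 replicate 3, but not all of the 11 were among the 22. Of the 22, the vitellogenins, lysozymes, UDP-glucuronosyltransferases, neuropeptides and mitochondrially encoded genes kept their call without that library. So did the DAF-16 repressed genes, the PMK-1 genes and the endoplasmic reticulum unfolded protein response, while all others of the 22 lost it. Called higher but not described above were complex I, complexes II to V, mitochondrial ribosomal proteins, glycolysis, the tricarboxylic acid cycle and neuronal genes. Oocyte and early zygotic genes were called lower. Each of these calls was lost without that library.

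The isp-1;sod-5 double mutant differed from isp-1 in 169 genes, with 90 higher and 79 lower, of which 49 and 55 changed at least 2-fold. Within the same limits, the largest rise was that of timm-17B.2, which encodes a protein of the mitochondrial import machinery, from 10.4 ± 1.43 to 105 ± 13.4 CPM (SD, n = 3 each, 9.64-fold, log2 3.27, SE 0.15, adjusted p = 9.47e-08). Then came fbxa-24 (6.82-fold, adjusted p = 0.00149), clec-43 (5.85-fold, adjusted p = 1.16e-05), clec-72 (3.43-fold, adjusted p = 0.00198), the ribonuclease H gene rnh-1.3 (3.23-fold, adjusted p = 0.000274), hrg-2 (2.69-fold, adjusted p = 0.00684) and dhs-25 (2.64-fold, adjusted p = 1.16e-05). The ion channel gene delm-2 rose 3.88-fold (adjusted p = 0.0208), a call lost without any one isp-1 library or without isp-1;sod-5 replicate 2 or 3 (up to 0.114). The largest falls within these limits were those of dod-24 (log2 −2.85, adjusted p = 7.82e-05) and vit-3, from 1010 ± 141 to 210 ± 61.8 CPM (log2 −2.3, adjusted p = 1.16e-05). They were followed by cyp-35C1 (log2 −2.03, adjusted p = 0.00107), vit-4 (log2 −1.81, adjusted p = 1.16e-05) and asp-14 (log2 −1.77, adjusted p = 0.00258). The zinc finger gene ztf-25 was 3.08-fold lower (adjusted p = 9.05e-05) and the immune gene irg-8 2.84-fold lower (adjusted p = 0.000293). The gene sysm-1, at log2 −1.64 (adjusted p = 0.0223), lost its call without any one isp-1 library or isp-1;sod-5 replicate 1 or 2 (up to 0.12). Of all tested genes 16.8% had no overlap of libraries, against 10% by chance. The count of 169 was 89, 90 and 92 without isp-1 replicate 1, 2 or 3, and 261 without isp-1;sod-3 replicate 2. The share of called genes that rose was 53.3%, against 42.4% with TMM factors, 45.4% with median centring, 45.5% with quantile normalization, 40.4% with the length trend removed and 49% with rrn-3.1 left out.

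Several lists of yolk, immune and detoxification genes were called lower in isp-1;sod-5 than in isp-1 as well, while the epidermal antimicrobial peptides and the peroxide and thiol antioxidants were called higher. Of 6 vitellogenins 0 rose and 4 fell, or 6 adjusted over the list alone (median log2 −1.28, camera adjusted p = 8.05e-13, and adjusted p = 0.209 with an estimated correlation). Their summed share of reads was 5.052, 3.891 and 2.965% in isp-1;sod-5, against 6.915, 5.358 and 6.158% in isp-1. Of 10 lysozymes 0 rose and 2 fell, or 4 adjusted over the list alone (median −0.46, camera adjusted p = 0.000129, and adjusted p = 0.209 with an estimated correlation), with ilys-5 at log2 −1.43. Of 17 DAF-16 repressed genes 0 rose and 3 fell, or 4 adjusted over the list alone (median −0.20, camera adjusted p = 3.33e-06, and adjusted p = 0.209 with an estimated correlation), including dod-24 and dct-17 (log2 −1.79). Of 25 PMK-1 genes 0 rose and 3 fell, or 1 and 7 adjusted over the list alone (median −0.12, camera adjusted p = 6.73e-05, and adjusted p = 0.482 with an estimated correlation). The 57 UDP-glucuronosyltransferases had 0 up and 3 down, or 1 and 5 adjusted over the list alone (median −0.21, camera adjusted p = 1.12e-05, and adjusted p = 0.637 with an estimated correlation). The 57 cytochrome P450 genes had 1 up and 4 down, or 1 and 9 adjusted over the list alone (median −0.05, camera adjusted p = 9.14e-05, and adjusted p = 0.482 with an estimated correlation), with cyp-25A1 at log2 −1.49 and cyp-34A8 at log2 0.84. The 26 SKN-1 targets had 0 up and 1 down, or 1 and 5 adjusted over the list alone (median −0.12, camera adjusted p = 0.00754, and adjusted p = 0.482 with an estimated correlation). The last 3 lists kept their calls without any one library, but their libraries overlapped. As mean log2 deviations, the cytochrome P450 genes were at −0.21, 0.21 and 0.29 in isp-1;sod-5 and 0.22, 0.17 and 0.1 in isp-1. The UDP-glucuronosyltransferases were at −0.34, 0.21 and 0.08 against 0.25, 0.24 and 0.07. The SKN-1 targets were at −0.03, 0.18 and 0.33 against 0.32, 0.27 and 0.27. Each time isp-1;sod-5 replicate 1 was lowest. The mitochondrial unfolded protein response list had 0 members changed, 1 up adjusted over the list alone (camera adjusted p = 0.146), with hsp-6 at log2 0.26 (adjusted p = 0.249). The epidermal antimicrobial peptide list had 2 up and 0 down of 12, or 3 and 1 adjusted over the list alone, with nlp-28 at log2 1.12 (adjusted p = 0.003). Its median of 0.43 and camera adjusted p = 0.0391 (adjusted p = 0.739 with an estimated correlation) became 0.17 and 0.127 without isp-1;sod-5 replicate 3. The call was also lost without isp-1 replicate 3, isp-1;sod-3 replicate 2, isp-1;sod-5 replicate 2 and with the length trend removed. Of 21 genes of the endoplasmic reticulum unfolded protein response 0 were called, also adjusted over the list alone. Their camera adjusted p = 0.0217 (adjusted p = 0.637 with an estimated correlation) was 0.31 without isp-1;sod-5 replicate 3, and the call was lost too without isp-1 replicate 1 and with the length trend removed. The 36 glutathione S-transferases had 0 up and 1 down, or 0 and 3 adjusted over the list alone, and were not called (camera adjusted p = 0.144). The 27 peroxide and thiol antioxidant genes had 1 up and 1 down, or 3 and 2 adjusted over the list alone, with the glutathione peroxidase gene gpx-8 up 4.75-fold (adjusted p = 0.000769). The list was called higher (median 0.15, camera adjusted p = 0.0406, and adjusted p = 0.637 with an estimated correlation). The call was lost without isp-1 replicate 2 or 3, isp-1;sod-3 replicate 2 or isp-1;sod-5 replicate 1 or 2 (up to 0.0824), with median centring (0.0776) and with the length trend removed (median 0.03, adjusted p = 0.499). The 21 HIF-1 genes had 1 up and 1 down in both double mutants (3 and 2, and 2 and 1, adjusted over the list alone, camera adjusted p = 0.402 for isp-1;sod-3 and 0.714 for isp-1;sod-5), with fmo-2 at log2 −1.31 (adjusted p = 0.00348, and 0.0509 with a pseudocount of 0.1 CPM) and −2.03 (adjusted p = 0.000104). The 19 iron and metal handling genes had 1 up and 0 down in both, namely hrg-1, the same adjusted over the list alone (camera adjusted p = 0.647 and 0.87). The 93 C-type lectins had 3 up and 3 down in isp-1;sod-5, or 3 and 7 adjusted over the list alone, with a median of −0.03 and the camera direction down (adjusted p = 0.0219, and adjusted p = 0.815 with an estimated correlation). That call was lost without isp-1 replicate 2 (median 0.01, adjusted p = 0.191) and without isp-1;sod-5 replicate 1 or 2 (medians 0.08 and −0.06).

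One library of this group differed from the others by gene length. In isp-1;sod-5 replicate 3 the log2 deviation of a gene from its 12-library mean fell with exon length (Spearman −0.59 across genes, which are not independent replicates), while the other libraries ranged from −0.03 to 0.17. The same library held 3370 CPM of the ribosomal RNA gene rrn-3.1, against 18100 to 71200 CPM elsewhere. Lists of short genes moved with it in the comparison of isp-1;sod-5 with isp-1, with 0 called members in each of the 5 lists, also adjusted over the list alone. The 81 cytosolic ribosomal protein genes had a median log2 of 0.31 (camera adjusted p = 2.56e-18, adjusted p = 0.637 with an estimated correlation), 0.19 without the library (adjusted p = 6.73e-13) and 0.14 with the length trend removed (adjusted p = 3.35e-07). Mitochondrial ribosomal proteins had a median of 0.21 (camera adjusted p = 1.02e-08), or 0.12 without the library. Nuclear genes of complex I were at 0.23 and of complexes II to V at 0.25 (camera adjusted p = 2e-06 and 9.5e-08), or 0.13 and 0.14 without it. These 3 lists also had an adjusted p = 0.637 with an estimated correlation. Neuropeptides were at 0.39 (camera adjusted p = 8.09e-11, adjusted p = 0.637 with an estimated correlation), or 0.17 without it (adjusted p = 0.000783).

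**Figure D4:**
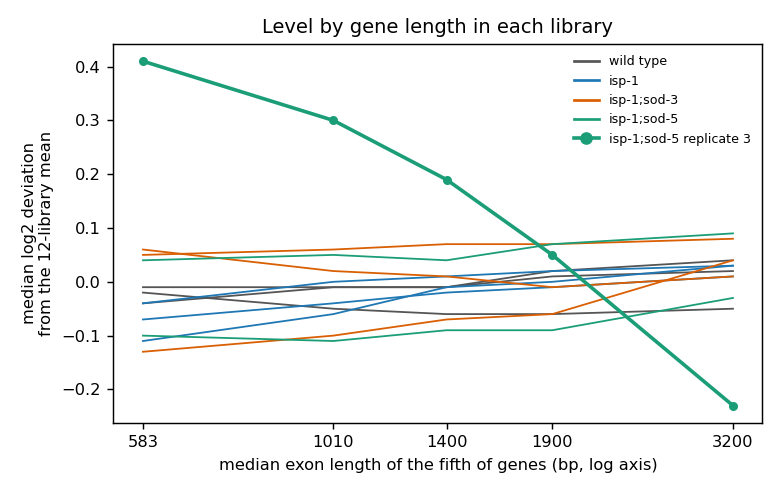
Median log2 deviation from the 12-library mean (vertical axis) of the genes in 5 groups of rising exon length (horizontal log axis, median length of each group in bp), with 1 line per library coloured by genotype. The thick line with points, isp-1;sod-5 replicate 3, runs from 0.41 at 583 bp to −0.23 at 3200 bp.

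Many genes differed from isp-1 in the same direction in both double mutants. Of the 152 and 169 genes called in the double mutants against isp-1, 96 were called in both, 51 up and 45 down, with 0 in opposite directions. Independent lists would share 0.501 and 0.417 genes, and 100 simulated regroupings with the same shared isp-1 libraries gave 0 in every draw. The simulations hold no effect, so hardly any gene is called in them, and the product leaves out the shared libraries. Neither value measures what the shared isp-1 libraries add to the 96, and part of the excess may come from them. Among the shared genes hrg-1 was 2.56-fold higher in isp-1;sod-3 and 2.53-fold higher in isp-1;sod-5 (adjusted p = 0.002 and 0.00223). The shared falls included dod-24, vit-3, vit-4, ilys-5 and fmo-2. The correlation of both sets of log2 fold changes across genes was 0.732, against a mean of 0.414 in the simulations, where the shared isp-1 libraries alone produce it. The covariance was 0.08 against 0.0278, a difference of 0.0522. The simulations mix the residuals of all genotypes. The median within-group SD was 0.13 in isp-1, against 0.22 in isp-1;sod-3 and 0.27 in isp-1;sod-5. The simulated values may thus overstate what the isp-1 libraries add. The count of 96 was 62, 61 and 62 without isp-1 replicate 1, 2 or 3.

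**Figure D5:**
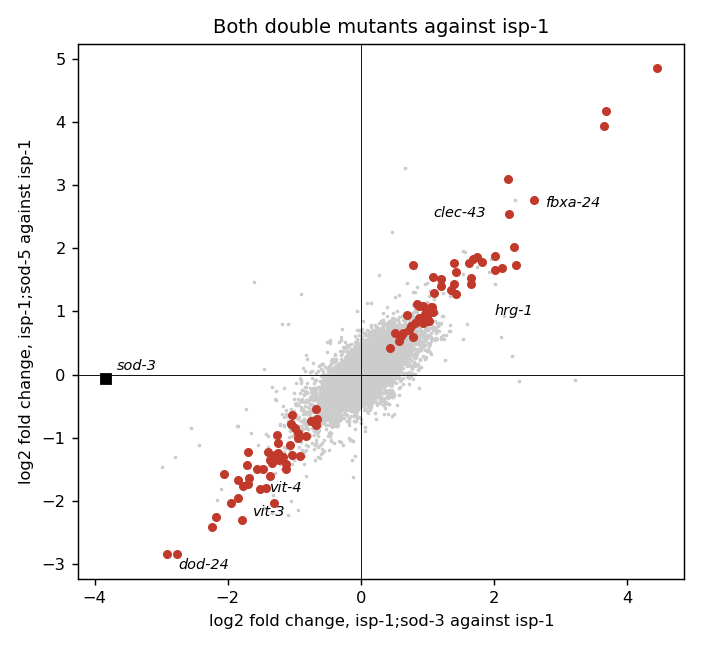
Log2 fold change against isp-1 of each tested gene in isp-1;sod-3 (horizontal axis) and isp-1;sod-5 (vertical axis), with the 96 genes called in both comparisons in red and sod-3 as a black square. All red points lie in the quadrants where both changes have the same sign, 51 up and 45 down.

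Genes altered in isp-1 moved both back and further in the double mutants. In isp-1;sod-3, 32 genes that had risen in isp-1 fell and 16 that had fallen rose, 48 in all, while 25 and 11 moved further in their isp-1 direction. In isp-1;sod-5, 36 and 13 genes moved back, 49 in all, and 38 and 12 moved further. Independent lists would give 7.1 and 8.09 genes moved back for the sod-3 double mutant and 7.58 and 9.33 for the sod-5 double mutant. For genes moved further they would give 7.49 and 7.67, and 8.64 and 8.19. The isp-1 libraries enter both comparisons with opposite sign, so these products are not the counts expected without an effect. In the simulations with no effect 0 genes moved back in any draw, and at most 0 and 5 moved further, where hardly any gene is called. The gene fmo-2 moved back in both double mutants, in isp-1;sod-3 not past the threshold with a pseudocount of 0.1 CPM, while hrg-1, vit-3 and ilys-5 moved further in both. The across-gene correlation of the isp-1 change with the change in isp-1;sod-3 was −0.319, against −0.501 in simulations with no effect, and with the change in isp-1;sod-5 it was −0.175 against −0.478. The covariance was −0.0674 against −0.0333 in isp-1;sod-3 and −0.0362 against −0.0314 in isp-1;sod-5, differences of −0.0341 and −0.00481. Shared libraries add the same covariance with or without effects, which does not hold for the correlation. As the simulations mix the residuals of all genotypes and isp-1 varied less than the double mutants, they may overstate this shared covariance. The difference of −0.00481 for isp-1;sod-5 therefore does not show that nothing beyond the shared libraries was present. The count of 48 was 30 and 31 without wild type replicate 2 or 3, 25 and 26 without isp-1 replicate 1 or 3, and 82 without isp-1;sod-3 replicate 2. The count of 49 was 26, 21 and 26 without wild type replicate 1, 2 or 3, 15, 22 and 20 without isp-1 replicate 1, 2 or 3, and 83 without isp-1;sod-3 replicate 2.

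The double mutants differed directly from each other in 15 genes, 4 higher and 11 lower in isp-1;sod-3. Apart from sod-3 (13.6-fold lower, log2 −3.77, adjusted p = 0.00063), timm-17B.2 was 6.08-fold lower in isp-1;sod-3, at 16.8 against 105 CPM (log2 −2.60, adjusted p = 2.9e-06). The gene ire-1 was at 59.6 against 134 CPM (log2 −1.15, adjusted p = 0.00063) and the ubiquitin ligase gene cul-5 at 33.7 against 68.4 CPM (log2 −1.01, adjusted p = 0.000677). The SKN-1 target dhs-8 was at 1.7 against 5.91 CPM (log2 −1.54, adjusted p = 0.00351). Higher in isp-1;sod-3 were the dynamin gene dyn-1, at 137 against 81.8 CPM (log2 0.74, adjusted p = 0.00199), and ztf-25, at 13.3 against 4.29 CPM (log2 1.51, adjusted p = 0.00063). Of all tested genes 5.2% had no overlap of libraries, against 10% by chance, and 528 genes had an unadjusted p under 0.05. With the 6 libraries of this comparison alone, 2 genes were called, and sod-3 was not among them, nor was sod-3 called with edgeR (adjusted p = 0.0597). Of 45 lists 14 were called, against 7 without isp-1;sod-5 replicate 1, each with an adjusted p = 0.935 with an estimated correlation. Those named next had 0 called members, also adjusted over the list alone. They were the cytosolic ribosomal proteins (median −0.17, camera adjusted p = 1.08e-10), the vitellogenins (median 0.29, camera adjusted p = 0.000528) and the neuropeptides (median −0.17, camera adjusted p = 0.000528). Without isp-1;sod-5 replicate 3 these medians were −0.06 (adjusted p = 0.00108), 0.13 (adjusted p = 0.198) and 0.04 (adjusted p = 0.204). The vitellogenin call was also lost without isp-1;sod-3 replicate 2, and that list and the neuropeptides lost it with the length trend removed.

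Against wild type, isp-1;sod-3 differed in 2379 genes (1458 higher and 921 lower) and isp-1;sod-5 in 3402 (1972 higher and 1430 lower). In isp-1;sod-5 sod-3 was 7.57-fold above wild type (adjusted p = 0.000184), and in isp-1;sod-3 it was at log2 −0.85 (adjusted p = 0.138). The last value was −0.28 (adjusted p = 0.486) without isp-1;sod-3 replicate 1 and −1.18 (adjusted p = 0.0397) without isp-1;sod-3 replicate 3. The dismutase gene sod-2 rose 1.32-fold in isp-1;sod-3 (adjusted p = 0.00702, not past the threshold with median centring) and 1.39-fold in isp-1;sod-5 (adjusted p = 0.00215). The isp-1 gene rose 1.34-fold in isp-1;sod-5 (adjusted p = 0.0154, and 0.0757 without wild type replicate 2) and was at log2 0.28 in isp-1;sod-3 (adjusted p = 0.0884, and 0.0273 without isp-1;sod-5 replicate 3). The share of called genes that rose depended on the scaling. It was 61.3% in isp-1;sod-3, against 44.7% with median centring, 50.9% with quantile normalization, 51.6% with TMM factors, 49.5% with the length trend removed and 66.7% with rrn-3.1 left out. In isp-1;sod-5 it was 58%, against 43.1% with median centring, 52.1% with quantile normalization, 45% with TMM factors, 47.2% with the length trend removed and 60.6% with rrn-3.1 left out. The count for isp-1;sod-3 was 1256, 1211 and 1500 without wild type replicate 1, 2 or 3 and 1525 without isp-1;sod-3 replicate 1, and that for isp-1;sod-5 was 1882, 1865 and 2212 without wild type replicate 1, 2 or 3.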

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

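The tests on shared isp-1 libraries, on a shared batch, on gene length, on rrn-3.1, on the share of germline and with the molting and muscle covariates were chosen only after the result was seen, while the splits of the libraries and the collagen covariate were chosen before. The double mutants differed from each other by a direct test (limma, isp-1;sod-3 against isp-1;sod-5, 3 libraries each) in 15 genes. The log2 fold changes were −3.77 for sod-3, −2.60 for timm-17B.2, −1.54 for dhs-8, −1.15 for ire-1, −1.01 for cul-5, 0.74 for dyn-1 and 1.51 for ztf-25. That of tcl-2 was −1.06, with an adjusted p of 0.0632 without isp-1;sod-5 replicate 2 and a call also lost without isp-1;sod-3 replicate 1 or 3. That of gpx-8 was −1.78, with an adjusted p of 0.153 without isp-1;sod-5 replicate 2, and was called only when all libraries, or all but isp-1;sod-3 replicate 2 or 3, were used. The other 6 genes were chosen after their values were seen. BE0003N10.6 was at −3.08 and F36G3.2 at 3.31, and both kept their call without any one library. D1014.6 was at −2.18, with an adjusted p of 0.0583 without isp-1;sod-5 replicate 3, and F40D4.13 at −0.95, with 0.0502 without isp-1;sod-3 replicate 1. The pseudogene R12C12.8 was at −0.88, with an adjusted p of 0.158 without isp-1;sod-3 replicate 1 and a call also lost without wild type replicate 1, any isp-1 library, isp-1;sod-3 replicate 2 or 3, or isp-1;sod-5 replicate 1 or 2. F49C12.4 was at 2.48, with an adjusted p of 0.254 without isp-1;sod-5 replicate 3 and a call lost without any one library except isp-1;sod-3 replicate 2.

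With 3 libraries against 3 there are 10 splits of the libraries, too few for a share under 0.05. The real split was the only 1 of the 10 to reach its count in 5 comparisons. These were 2798 genes for isp-1 against wild type with 3 in the highest other split, 152 and 169 for the double mutants against isp-1 with 0 in the other splits, and 2379 and 3402 for the double mutants against wild type, again with 0. Between the double mutants 3 of the 10 splits, the real one included, gave at least the real 15 genes. The highest other split gave 634 genes and set isp-1;sod-3 replicates 1 and 3 with isp-1;sod-5 replicate 2 against the rest. It points to a structure of the samples, and its sides had mean collagen deviations of 0.09, 0.81 and 0.16 against −0.67, −0.53 and 0.20.

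The first pattern is the set of 96 genes that differed from isp-1 in the same direction in both double mutants. Chance values of the isp-1 libraries, which both comparisons share, may add to it. Of the 96, 74 were called in the same direction in both double mutants against wild type, where no isp-1 library enters, and 16 in neither. From all genes 6.95 were expected (exact binomial p = 2.28e-64, with genes not independent). In isp-1 against wild type 28 of the 96 were called in the same direction, 29 in the opposite direction and 39 not. The 96 were chosen with the same double mutant libraries, and genes changed in isp-1 can pass whatever its libraries did by chance. The 6.95 allows for neither, so the test does not decide this. A culture or library batch shared by the double mutants cannot be told apart from genotype, since no label gives a batch and only 15 genes differed between the double mutants. A common response to the loss of either dismutase may be the source and also stays open, untested.

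The second pattern is the set of lists of short genes (322 members, median exon length 644 bp against 1400 bp for all genes) that lay lower in isp-1;sod-3 than in isp-1;sod-5, with a median log2 of −0.16 over all members. That median was −0.03 without isp-1;sod-5 replicate 3, so the values go with the gene-length trend of that library, a candidate explanation found and tested on the same data. With the abundant rrn-3.1 left out of the totals the median was −0.14. Leaving out 1 gene rescales all genes of a library alike, and the median over all genes shifted by only 0.02. This scaling is thus too small to account for the −0.16, which follows from the arithmetic and is no independent test. For the same lists in isp-1;sod-5 against isp-1 the median was 0.29, with 0.16 without the library and 0.12 with the length trend removed from every library, so the trend could account for part of it and the rest stays open. No biological explanation was tested.

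The third pattern is the lower level of sperm genes in isp-1. A smaller share of germline as the whole cause is argued against, since the germline mitosis and meiosis list had a median log2 of −0.02. With a covariate the mean of that list was lower in isp-1, at −0.12 (95% interval −0.17 to −0.06) with the collagens, −0.13 (−0.22 to −0.03) with the molting genes and −0.12 (−0.20 to −0.04) with the muscle genes, so a small part is not excluded. A developmental axis was read only from the mean levels of collagen, molting and muscle genes, used as covariates. The mean of the 40 sperm genes outside the major sperm proteins differed by −1.0 between isp-1 and wild type on the log2 scale (95% interval −1.70 to −0.30). With the collagen mean as covariate it differed by −0.57 (−0.75 to −0.40). That interval excludes 0, the outcome set beforehand as speaking against the axis as the whole cause. The collagens themselves changed in isp-1, so their mean may misplace isp-1 on the axis, and the test does not decide the question. The major sperm proteins were at −0.62 (−0.98 to −0.26) with the collagens, −0.57 (−1.04 to −0.10) with the muscle genes and −0.59 (−1.26 to 0.09) with the molting genes as covariate. Their first 2 intervals also exclude 0, and the last includes it. The molting and muscle lists were also called lower in isp-1, so these intervals do not decide the question either. The isp-1 genotype itself and a difference in developmental timing may both contribute and stay open, since the collagens also changed in isp-1.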

How the results depend on the processing

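The tests with library weights, with the gene-length trend removed and with rrn-3.1 left out were chosen only after the result was seen. For each result below that moved by more than 1.5 times the cause was not tested, except that stricter thresholds, filters and fits with fewer libraries call fewer genes by construction or change the error estimate. For isp-1 against wild type the 2798 genes became 1792 with CPM above 5, 5702 with only the 2 groups fitted, 890 at an adjusted p below 0.01, 1480 with a 2-fold minimum, 7284 with library weights, and 1088 to 3581 with a library left out. The 152 genes of isp-1;sod-3 against isp-1 became 91, 96, 1209 and 250 with adjusted p below 0.01, a 2-fold minimum, library weights and the length trend removed, 323 with DESeq2, and 89 to 228 with a library left out. The 169 genes of isp-1;sod-5 against isp-1 became 89 with adjusted p below 0.01, 1.0e+02 with a 2-fold minimum (49 higher and 55 lower), 286 with library weights, 265 with the length trend removed, 337 with DESeq2, and 89 to 261. The 15 genes between the double mutants became 2 with only the 2 groups fitted, 28 with DESeq2 and 25 with library weights. Against wild type, isp-1;sod-3 gave 1039, 998 and 7455 genes at an adjusted p below 0.01, with a 2-fold minimum and with weights, and 1211 to 3525 with a library left out, and isp-1;sod-5 gave 1456 and 1447, and 1865 to 4162. Genes moved back numbered 517 and 124 with weights and 79 and 84 with the length trend removed for isp-1;sod-3 and isp-1;sod-5, 31 with CPM above 5 for isp-1;sod-5, and 25 to 82 and 15 to 83 with a library left out. The 96 genes shared by both double mutants became 60 with only the 2 groups fitted, 250 with weights, 155 with the length trend removed and 61 to 122 with a library left out. The estimation of weights stopped before convergence. With an estimated correlation camera called 0 lists in each comparison except isp-1;sod-3 against wild type, which had 1 (the mitochondrial unfolded protein response, adjusted p = 0.0499), while 27, 22, 19, 14, 22 and 26 were called with the preset correlation. With fry 3 lists were called for isp-1;sod-3 against isp-1, 4 for isp-1;sod-5 against isp-1 and 0 between the double mutants. With a library left out 11 to 28 lists were called for isp-1;sod-3 against isp-1 and 7 to 14 between the double mutants. The other counts, among them those with a replicate block, edgeR, other pseudocounts and other scalings, stayed within 1.5 times. For 244 pairs of a named gene and a comparison, 6488 of 7064 values under the alternatives kept their direction and their side of the threshold, 488 were no longer past it, 70 newly passed it, 18 changed sign without being past the threshold in either fit, and 0 called values changed sign. Depth limits the lowest genes, since 1 read is 0.184 CPM in the shallowest library.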

Other observations

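Both groups of genes here were put together only after the result was seen, and the p-values do not account for that choice. Of their tests, those on hrg-7, hrg-9, hrg-3, acdh-1, hach-1 and alh-8 were chosen only then, while hrg-1, hrg-2, hrg-4, hphd-1 and ech-6 were also named in some comparison by the fixed naming rule. Of 6 genes linked to heme, the iron-containing cofactor that C. elegans takes up from its food, hrg-1, hrg-2 and hrg-7 rose in isp-1 and further in both double mutants. No list of such genes was tested. The heme transporter gene hrg-1 was at 17.2 CPM in wild type, 37.4 in isp-1, 94.6 in isp-1;sod-3 and 93.1 in isp-1;sod-5 (3 libraries each). The gene hrg-2 was at 1.78, 13.3, 36.6 and 37.7 CPM in the same order, with an adjusted p of 0.0513 for isp-1;sod-3 against isp-1 without isp-1 replicate 3. The gene hrg-7, which encodes a secreted protease-like signal, was at 248 ± 28.5, 442 ± 49.1, 874 ± 64.3 and 842 ± 78.3 CPM (SD). Its log2 fold change was 0.84 in isp-1 against wild type (SE 0.12, limma adjusted p = 0.000619), 0.99 in isp-1;sod-3 against isp-1 (adjusted p = 0.000623) and 0.93 in isp-1;sod-5 against isp-1 (adjusted p = 0.00111). The gene hrg-9 rose in isp-1 (log2 1.93, adjusted p = 8.57e-05) and was at log2 −0.05 and 0.10 in the double mutants against isp-1. The genes hrg-3 and hrg-4 did not pass the test in these comparisons.

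Of 5 genes of the propionate shunt, which breaks down propionate when the vitamin B12 dependent route is not used, hach-1 and hphd-1 were higher in both double mutants than in isp-1 and kept these calls without any one library. This group was not tested as a list. The hydrolase gene hach-1 was at 340 ± 4.06 CPM in wild type, 170 ± 17.9 in isp-1, 310 ± 29.2 in isp-1;sod-3 and 304 ± 7.9 in isp-1;sod-5. It was lower in isp-1 than in wild type (log2 −1.0, adjusted p = 3.36e-05) and higher in the double mutants than in isp-1 (log2 0.86 and 0.84, adjusted p = 0.000438 and 0.000553). The dehydrogenase gene hphd-1 was at 491, 372, 723 and 725 CPM, with log2 0.96 in both double mutants against isp-1 (adjusted p = 0.000248 and 0.000274). Its fall in isp-1 (log2 −0.40, adjusted p = 0.0196) was lost without wild type replicate 2 or 3 or isp-1 replicate 1 or 3, up to 0.0962. The hydratase gene ech-6 rose by log2 0.63 and 0.65 (adjusted p = 0.0106 and 0.00923), calls lost without isp-1 replicate 3 (0.0926 and 0.0757) and, for isp-1;sod-3, also without isp-1 replicate 2 or isp-1;sod-3 replicate 1. The genes acdh-1 (log2 0.48 and 0.50, adjusted p = 0.0795 and 0.0619) and alh-8 (log2 0.42 and 0.41, adjusted p = 0.0619 and 0.066) did not pass.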
